A study of Arabidopsis thaliana with 10 samples.

How the data were processed

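The samples were polyA RNA libraries from whole Col-0 Arabidopsis thaliana seedlings of 3 kinds of line, titled GFP, DIG1 and DIG2, all given dexamethasone, a synthetic glucocorticoid used to switch on transgenes placed under its control. There were 5 groups of 2 replicates, 10 libraries in all. The first 3 groups (GFP, DIG1 and DIG2) were seedlings kept in the dark to an age of 3 d and then given 10 µM dexamethasone for 4 h without light. The other two groups (GFP and DIG1) were light-grown seedlings kept on plates with 500 nM dexamethasone for 10 d. Per the labels' protocols, libraries were made with a stranded mRNA kit and sequenced on an Illumina instrument. The growth and treatment texts of the labels give different units for the dose in the plates, and the dose printed here is the one that appears in the treatment text and in the sample characteristics. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

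The authors deposited 1 table for each experiment. Per the file headers, each holds an RPKM value (reads scaled to gene length and library size) for every gene and library, and, for each line compared with GFP, a log2 fold change and an FDR, which is an adjusted p-value. Per the submitters' processing notes the tools included HTSeq 0.5.4 and edgeR 3.6.2 and the genome build was TAIR10; the aligner was not given in the sources used here. The table for 4 h lists 17371 genes and that for 10 d lists 17433 genes. Columns were joined to samples by name; the columns name the lines with another abbreviation and the same numbers 1 and 2. The tables were normalized separately, so every test of expression was run within 1 table, called genes were compared between tables by Fisher's exact test and log2 changes by their correlation and sign, and levels are not compared between 4 h and 10 d. Gene symbols came from the TAIR10.1 annotation, matched on the locus, which found 17305 and 17386 genes.

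Because the deposited RPKM values keep many decimals, whole read numbers could be worked out from the steps between libraries, with a tolerance of 0.001 read. This gave whole reads for 99.94% of genes in the 4 h table and 99.81% in the 10 d table. The recovered reads were used for depth, for the noise between replicates and for 1 alternative test, never for the main tests. All but 10 of 17360 genes at 4 h, and all but 68 of 17400 at 10 d, reached 2 CPM (reads scaled to library size) in at least 2 libraries, so genes with lower levels were largely left out of both tables before any test here.

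RPKM values were put on the scale log2(RPKM + 0.5) and tested with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes variances with a trend on mean level, two-sided, Benjamini-Hochberg adjustment over all genes of the table, threshold 0.05). Fold changes on this scale understate the change of genes with low values. The 4 h comparisons were fitted on all 6 libraries, with the 3 groups sharing 1 estimate of the spread, and the 10 d comparison on its 4 libraries. Tested on simulated data, the 4 h fit (17371 genes, DIG1 against GFP) recovered 92.4% of genes changed 2-fold and 99.8% of those changed 4-fold, with 4.67% of calls false. For the 10 d fit (17433 genes) the shares were 43.2% and 91.2%, with 3.31% of calls false. In each of 5 simulated sets, 200 genes above a mean level were changed by those known amounts. Noise was drawn from the variance distribution that the fit itself estimates. The real comparisons with GFP called more genes than that, 10999 of them at 10 d, which loosens the threshold on unadjusted p. The simulated shares therefore need not hold for the real data.

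Gene lists were written before the data were examined, as were the comparisons, the tests, the rule for naming genes and all but 1 of the alternatives. The 26 lists hold 315 genes. They cover abscisic acid (ABA) signalling, synthesis and response, osmolytes and aquaporins, photosynthesis and light response, cell wall loosening, hormones, defence, heat, cold and touch, senescence, flavonoids, the cell cycle, the clock, and markers of root and guard cells. The transgenes and the relatives of the DIG genes were reported gene by gene, and a seed maturation list had 0 measured members at 4 h and 1 at 10 d, which left 23 lists for testing. Lists were tested with camera from limma (preset correlation between genes of 0.01, two-sided, adjusted over the 23 lists). Camera compares a list with all other genes. It was run again with the correlation estimated from the data, and fry from limma was run as a test of whether a list's genes move one way on balance.

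For each comparison with GFP, the named genes were the 8 with the largest fold change in each direction (5 for DIG1 against DIG2) among genes with an adjusted p under 0.05, both libraries of 1 group above both of the other, a mean of at least 1 RPKM and a symbol. Up to 4 called members of each list with a camera call or at least 3 called members were added, with the transgenes and their relatives. Overlaps between comparisons that share the GFP libraries were set beside 50 simulated sets of unchanged lines.

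The alternatives were pseudocounts of 0.1 and 2 RPKM, a mean of at least 1 RPKM, quantile normalization, a median shift, variances without the trend, robust variances, fits on only the 2 groups compared, a replicate block, each library left out in turn, a 2-fold minimum, and, for lists, an estimated correlation and fry. Limma's voom weights on the recovered reads were added after seeing the data. With 1 library left out, the lone sample of its group was assumed to vary like the other groups. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.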

Results

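The transcriptomes of seedlings from dexamethasone-treated GFP, DIG1 and DIG2 lines were measured by RNA-seq in 5 groups of 2 libraries. The series describes DIG proteins as transcription factors that respond to ABA, the hormone of drought and seed dormancy. The question was which genes differ from GFP in dark-grown DIG1 or DIG2 seedlings given dexamethasone for 4 h. It was also which differ after light-grown DIG1 seedlings have spent 10 d on dexamethasone. All libraries came from treated seedlings, so differences of a line present before treatment cannot be told apart from effects of induction. Below, rose and fell mean higher and lower than in GFP. The recovered reads on listed genes came to 13003244 and 12062930 for GFP at 4 h, 9481472 and 9841051 for DIG1 and 15048677 and 12431057 for DIG2. At 10 d they came to 11232038 and 16867093 for GFP and 12576479 and 15745649 for DIG1. Replicates correlated at a Pearson r between 0.985 (DIG1 at 10 d) and 0.992 (GFP at 4 h) across genes, which are not independent replicates. They differed by more than sampling noise in every group, with a chi-square per degree of freedom from 4.67 to 10.5 on the recovered reads, so no library was a copy of another. All values below are RPKM as mean ± SD with n = 2, and fold changes are on the log2(RPKM + 0.5) scale with their standard error.

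The gene known by the name in the titles, DIG1 or DIG2, was high in the libraries of that line. AT3G48510, known as DIG1 (chromosome 3, 17967354 to 17968590, TAIR10.1), stood at 1716 and 1438 RPKM in the DIG1 libraries at 4 h, against 0.551 and 1.43 in GFP and 1.90 and 1.54 in DIG2. At 10 d it stood at 1891 and 1775 RPKM in DIG1 and at 1.42 and 0.935 in GFP. Its log2 change against GFP was 10.11 ± 0.23 at 4 h (limma adjusted p = 1.75e-08) and 10.11 ± 0.16 at 10 d (limma adjusted p = 0.000155). The titles of the DIG1 samples print another locus, AT3G45810. No value was at hand for it, so the locus in those titles was not shown to be high. AT5G50360, known as DIG2 (chromosome 5, 20505089 to 20506354, TAIR10.1), stood at 4879 and 2685 RPKM in the DIG2 libraries, against 0.876 and 0.768 in GFP and 2.54 and 1.23 in DIG1. Neither gene passed the test in the other line, with limma adjusted p = 0.121 for DIG2 in the DIG1 line and 0.0983 for DIG1 in the DIG2 line. Of the family relatives, AT5G63350 did not pass the test at 4 h in either line. AT3G27250 fell at 10 d from 3.11 ± 1.23 to 0.0564 ± 0.0797 RPKM (limma adjusted p = 0.00149).

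**Figure D1:**
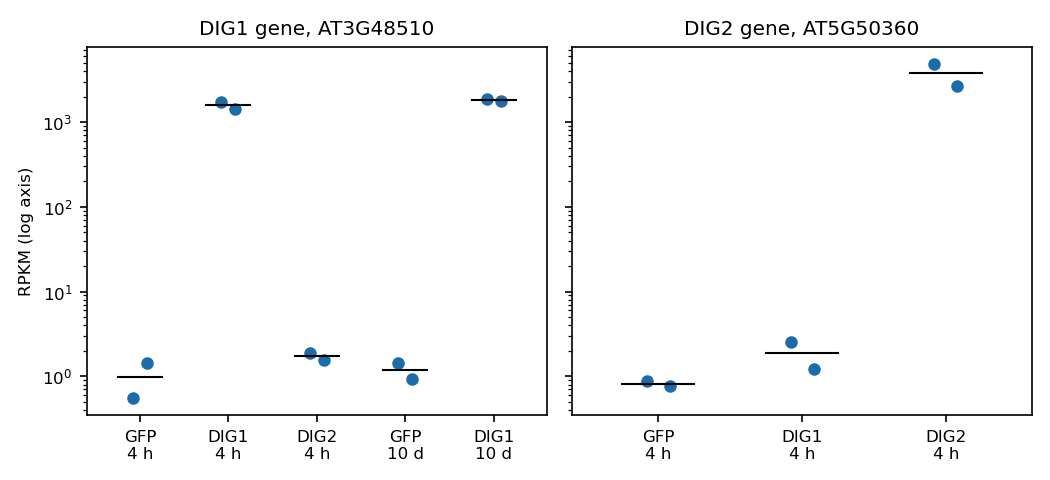
RPKM (log axis) of AT3G48510 in 5 groups and of AT5G50360 in the 3 groups at 4 h; points are libraries and bars are group means. The lowest DIG1 library lies at 1438 RPKM for AT3G48510 and the lowest DIG2 library at 2685 RPKM for AT5G50360, and the highest of the other libraries drawn lies at 2.54 RPKM.

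After 4 h of dexamethasone in the dark, DIG1 seedlings had lower transcripts of PORA, PORB and the B-box genes BBX23 and BBX17 than GFP seedlings. PORA, the protochlorophyllide oxidoreductase of dark-grown seedlings, fell from 929.9 ± 71.7 to 73.0 ± 12.1 RPKM (log2 change −3.67 ± 0.14, limma adjusted p = 4.53e-07). Its relative PORB fell from 1642 ± 80.5 to 475 ± 33.1 RPKM. BBX23 fell from 36.8 ± 2.34 to 0.893 ± 0.194 RPKM (−4.75 ± 0.15, limma adjusted p = 2.32e-07) and BBX17 from 64.2 ± 7.61 to 7.22 ± 1.32. RD20, a drought-induced calcium-binding lipid-body protein, fell from 10.3 ± 3.84 to 0.386 ± 0.112 RPKM. In the other direction, the defence gene PR1 rose from 0.516 ± 0.325 to 4.25 ± 0.0243 RPKM and the peptide transporter gene OPT1 from 10.4 ± 1.34 to 29.5 ± 5.36.

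The other largest falls were in HEC1, TCL2, FLP1 and HSP22, with log2 changes from −2.97 to −2.49. The other largest rises were in BGLU19, RD29B, LPR1, PER4, EXPA2 and BETA-TIP, with log2 changes from 1.56 to 2.07. By the rule for naming genes, both DIG1 libraries lay beyond both GFP libraries in each of these 16 genes. The calls of RD29B and EXPA2 were lost in some fits without 1 library. RD29B, at 13.5 ± 11.8 RPKM in DIG1, lost its call without GFP replicate 1 or GFP replicate 2, and EXPA2 without DIG1 replicate 1. Such fits have fewer samples, so a lost call does not single out the library left out. RD29B stood at 21.8 and 5.10 RPKM in the DIG1 libraries, against 2.85 and 1.93 in GFP.

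By group, the light response list moved most. Of its 8 measured genes, 6 fell and 1 rose, both over all genes tested and adjusted over the list alone, with a mean log2 change of −1.03 (camera adjusted p = 8.30e-06). With an estimated correlation its camera adjusted p = 0.362, and by fry it passed (adjusted p = 0.00204). The gene that rose, named after its values were seen, was HY5, a bZIP factor that promotes light responses (log2 change 0.79, limma adjusted p = 0.0108), and its call was lost without GFP replicate 1 or either DIG1 library (limma adjusted p up to 0.0737). ELIP2 fell by 1.38 on the log2 scale and PIL1 by 1.03. Of 20 measured photosynthesis genes, 5 fell over all genes tested and 9 adjusted over the list alone, none rose, and the mean log2 change was −0.66 (camera adjusted p = 9.72e-07; camera adjusted p = 0.9398 with an estimated correlation). By fry the photosynthesis list did not pass (adjusted p = 0.140). LHCB2.1, a light-harvesting protein gene, fell from 576 ± 17 to 224 ± 42.5 RPKM (limma adjusted p = 0.000542). Guard cell markers moved with these lists and passed fry (adjusted p = 0.0345). Their 4 measured genes had a mean log2 change of −0.59 (camera adjusted p = 0.0227; camera adjusted p = 0.654 with an estimated correlation), and 1 of them, the potassium channel gene KAT1, fell over all genes tested, from 12.2 ± 0.61 to 5.06 ± 1.09 RPKM. The guard cell call was lost without GFP replicate 1 or DIG1 replicate 2, with a camera adjusted p of up to 0.0991.

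ABA-related genes moved in both directions in DIG1 at 4 h. Among 12 measured ABA- and drought-induced genes, RD29A rose from 15.6 ± 1.99 to 32.2 ± 0.694 RPKM and COR6.6 fell from 17.8 ± 4.09 to 3.12 ± 0.0662. In all, 2 rose and 3 fell (4 and 3 adjusted over the list alone). DIG1 replicate 1 stood apart in some of these genes, picked after their values were seen. RAB18, a dehydrin gene, was at 242 RPKM in it against 3.23 in DIG1 replicate 2 and 5.58 and 2.75 in GFP, and LEA4-5 at 93.7 against 4.07 in DIG1 replicate 2 and 2.96 and 2.08 in GFP. RD29B, which was called higher, was at 21.8 RPKM in it against 5.10 in DIG1 replicate 2 and 2.85 and 1.93 in GFP. The mean log2 change of the list was −0.41 without DIG1 replicate 1 and 0.75 without DIG1 replicate 2. Of 23 ABA transcription factors, 2 rose and 2 fell (3 and 3 adjusted over the list alone). ABF3, a bZIP factor of ABA response, fell from 63.8 ± 0.651 to 21.8 ± 0.626 RPKM (limma adjusted p = 1.51e-05) and NAC032 rose from 2.73 ± 0.176 to 7.40 ± 1.09. Neither list passed camera (adjusted p = 0.892 for both), and their signs were mixed: the first had a mean of 0.17 while camera pointed down, and the second a mean of −0.01, a median of 0.13 and camera pointing up. ABI3, a transcription factor of seed maturation in the second list, was likewise at 4.83 RPKM in DIG1 replicate 1 against 0.538 in DIG1 replicate 2. Of 14 measured genes for cell wall loosening, 5 fell, XTH9, XTH17 and XTH19 among them, and 2 rose, including EXPA1 (5 and 3 adjusted over the list alone, camera adjusted p = 0.405). Of 16 auxin response genes 1 rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.759). IAA19, an auxin-response repressor, fell by 1.15 on the log2 scale, while IAA1 rose by 0.69. Of 8 measured jasmonate genes 1 rose and 2 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.405). The jasmonate-response repressor gene JAZ1 fell by 1.41, while JAZ7 rose by 0.80. Of 12 circadian clock genes 3 rose (BOA, RVE8 and TOC1) and 2 fell (GI and CCA1, the latter named after its values were seen), with 6 and 2 adjusted over the list alone (mean 0.21, camera adjusted p = 0.164, fry adjusted p = 0.00367). Each of these 5 calls was lost without some library (limma adjusted p up to 0.173): TOC1, GI and CCA1 without any of the 4, RVE8 without either GFP library or DIG1 replicate 2, and BOA without GFP replicate 1 or DIG1 replicate 2. Of 7 measured genes of ABA synthesis and turnover none rose and 2 fell, NCED3 and CYP707A1, both named after their values were seen, with the same counts adjusted over the list alone (mean −0.25, camera adjusted p = 0.779, fry adjusted p = 0.0345). The call of CYP707A1 was lost without either GFP library or DIG1 replicate 1 (limma adjusted p up to 0.114). Of 7 measured root markers 1 rose and 2 fell (1 and 4 adjusted over the list alone), with a mean log2 change of −0.37 (camera adjusted p = 0.173).

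Over 17371 genes, 522 rose and 962 fell in DIG1 at 4 h, of which 75 and 263 changed at least 2-fold. These counts fell with any library left out, in fits that have fewer samples. They were 254 and 493 without GFP replicate 1, 141 and 335 without GFP replicate 2, 230 and 587 without DIG1 replicate 1, and 230 and 454 without DIG1 replicate 2; without the variance trend 329 genes rose.

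After 4 h DIG2 seedlings had lower transcripts of RD20, COR6.6, ELIP2 and LUT2 than GFP seedlings, and higher transcripts of NRT2.6, NRT1.8 and DIN2. RD20 fell from 10.3 ± 3.84 to 0.490 ± 0.124 RPKM (log2 change −3.41 ± 0.26, limma adjusted p = 8.59e-05) and COR6.6 from 17.8 ± 4.09 to 1.25 ± 0.131 (−3.37 ± 0.18). ELIP2, a light-induced chloroplast protein, fell from 20.2 ± 0.693 to 2.61 ± 0.0715 RPKM, and LUT2, of carotenoid synthesis, from 32.8 ± 1.87 to 5.46 ± 0.543. The nitrate transporter gene NRT2.6 rose from 0.429 ± 0.232 to 9.08 ± 1.95 RPKM (3.37 ± 0.24, limma adjusted p = 6.03e-05), NRT1.8 from 9.0 ± 0.462 to 43.9 ± 10.7, and DIN2, a beta-glucosidase gene induced in darkness, from 117 ± 24 to 460.0 ± 53.4.

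The other largest falls were in BBX14, BBX23, CYP79B2 and GH9B1, with log2 changes from −2.32 to −2.28. The other largest rises were in RD29B, HIS1-3, COR27, HOL2 and GH3.1, with log2 changes from 1.64 to 2.36. By the rule for naming genes, both DIG2 libraries lay beyond both GFP libraries in each of these genes. RD29B and HIS1-3 each reached a limma adjusted p of 0.0633 without 1 library (GFP replicate 2 or DIG2 replicate 1 for RD29B, GFP replicate 1 or DIG2 replicate 1 for HIS1-3).

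The photosynthesis list had a mean log2 change of −0.76 in DIG2, with 8 of 20 genes lower over all genes tested and 9 adjusted over the list alone, and none higher (camera adjusted p = 1.98e-06; camera adjusted p = 0.744 with an estimated correlation), and it did not pass fry (adjusted p = 0.0667). LHCB1.4 fell from 664 ± 81.1 to 208 ± 19.6 RPKM and RBCS1B, a Rubisco subunit gene, from 415 ± 3.49 to 167 ± 31.9. In the light response list 5 of 8 genes fell and 1, HY5, rose, with the same counts adjusted over the list alone (mean −0.86, camera adjusted p = 0.00759; camera adjusted p = 0.414 with an estimated correlation). Guard cell markers had a mean log2 change of −0.63 over 4 genes, 2 of them lower over all genes and 3 adjusted over the list alone (camera adjusted p = 0.0361; camera adjusted p = 0.425 with an estimated correlation). KAT1 fell from 12.2 ± 0.61 to 4.62 ± 0.679 RPKM. By fry the light response and guard cell lists passed (adjusted p = 0.0033 and 0.0359). The guard cell call was lost, at a camera adjusted p of up to 0.0559, without GFP replicate 1 or DIG2 replicate 2.

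More auxin response genes rose than fell in DIG2. Over all genes tested, 7 of 16 rose and 2 fell, and adjusted over the list alone 13 rose and 2 fell (mean 0.30, camera adjusted p = 0.000391; camera adjusted p = 0.414 with an estimated correlation; fry adjusted p = 0.0517). IAA1 rose from 15.2 ± 2.11 to 33.5 ± 2.64 RPKM and SAUR22 from 24.2 ± 0.00693 to 37.8 ± 4.01, while IAA19 fell from 110.9 ± 4.22 to 46.7 ± 10.3. Cell division genes were lower, with 4 of 11 falling over all genes and 8 adjusted over the list alone (mean −0.43, camera adjusted p = 0.00227). With an estimated correlation their camera adjusted p = 0.414, and by fry they passed (adjusted p = 0.0161). Of the 12 clock genes, which fry also called in DIG1, 4 rose and 3 fell in DIG2 (7 and 4 adjusted over the list alone; mean 0.16, camera adjusted p = 0.235, fry adjusted p = 0.0161). CCA1 and LHY fell by 1.59 and 0.80 on the log2 scale, and TOC1 rose by 0.73. BOA, ELF3 and ELF4 also rose and GI fell; ELF3, ELF4 and GI were named after their values were seen. The calls of ELF3, ELF4 and GI were lost without 1 library (limma adjusted p up to 0.147, 0.0891 and 0.123; GFP replicate 1 for each, GFP replicate 2 or DIG2 replicate 1 for ELF3 and GI, DIG2 replicate 2 for ELF4).

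ABA- and drought-induced genes moved in both directions in DIG2 as well, 2 of 12 rising, RD29A among them, and 3 falling (2 and 4 adjusted over the list alone; mean −0.21, median 0.21, camera pointing down with adjusted p = 0.482). Of 23 ABA transcription factors 5 rose and 5 fell (8 and 5 adjusted over the list alone; mean −0.07, median 0.13, camera pointing up with adjusted p = 0.756). ABF3 fell from 63.8 ± 0.651 to 19.9 ± 1.04 RPKM, and the proline synthesis gene P5CS1 from 14.3 ± 2.87 to 5.01 ± 0.889. PRODH1, of proline breakdown, rose from 160.2 ± 1.66 to 300.4 ± 5.27 RPKM. Among SnRK2 kinase genes, which act in ABA and osmotic signalling, 3 of 10 rose and 1, SNRK2.5, fell, with the same counts adjusted over the list alone (camera adjusted p = 0.235).

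In DIG2 at 4 h 1281 genes rose and 1300 fell, of which 107 and 273 changed at least 2-fold. The counts were 484 and 550 without GFP replicate 1, 406 and 509 without GFP replicate 2, and 412 and 573 without DIG2 replicate 1; without the variance trend 762 genes rose.

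The direct contrast of the lines asked which effects of DIG1 and DIG2 differed at 4 h. NRT2.6 was lower in DIG1 (0.693 ± 0.155 RPKM) than in DIG2 (9.08 ± 1.95), a log2 difference of −3.00 ± 0.24 (limma adjusted p = 0.000594). BBX23 and BBX17 fell in both lines, further in DIG1, with log2 differences of −2.44 ± 0.15 and −2.0 ± 0.15. PORA likewise fell in both and further in DIG1, to 73.0 ± 12.1 against 194.8 ± 8.3 RPKM. ELIP2 fell in both and further in DIG2, at 7.42 ± 0.158 in DIG1 against 2.61 ± 0.0715. UMAMIT25, a transporter gene, rose in DIG1 and fell in DIG2 (limma adjusted p against GFP = 0.0492 and 0.0184). It stood at 4.57 ± 1.24 RPKM in DIG1 against 0.926 ± 0.264 in DIG2 (log2 difference 1.82 ± 0.23, limma adjusted p = 0.00487). PIL1, at 12.3 ± 0.432 RPKM in DIG1 and 25.5 ± 0.179 in DIG2, and XTH19 were lower in DIG1.

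The other largest differences were higher in DIG1 for EXPA2, PR1 and GSTF6 and lower for PGAZAT and GH3.1, and each of these 5 calls was lost without some library. The call of EXPA2 was lost without any of the 4 libraries (limma adjusted p up to 0.192). Those of PR1 (up to 0.141) and GSTF6 (up to 0.0791) were lost without DIG1 replicate 1, DIG1 replicate 2 or DIG2 replicate 1, that of PGAZAT without either DIG1 library (up to 0.138) and that of GH3.1 without DIG1 replicate 1 (0.0606), all by limma.

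By group, auxin response genes were lower in DIG1 than in DIG2 (mean −0.35 over 16 genes, 2 lower over all genes tested and 6 adjusted over the list alone, camera adjusted p = 7.22e-05; camera adjusted p = 0.469 with an estimated correlation). Cell division genes were higher in DIG1 (mean 0.27 over 11 genes, 0 called over all genes and 2 higher adjusted over the list alone, camera adjusted p = 0.00413; camera adjusted p = 0.469 with an estimated correlation). Another 6 lists passed camera with the preset correlation and lost the call without some library. Senescence genes were lower in DIG1 (mean −0.36, 1 lower over all genes and 4 adjusted over the list alone), and the call was lost without DIG2 replicate 1 (camera adjusted p = 0.113). Jasmonate genes were lower (−0.34, 1 and 3 adjusted over the list alone), not so called without DIG1 replicate 1 (0.0624). Root markers were lower (−0.39, 0 and 3 adjusted over the list alone), not so called without DIG1 replicate 1 or DIG2 replicate 2 (up to 0.576). Cell wall loosening was lower (−0.24, 1 and 3 adjusted over the list alone), not so called without DIG2 replicate 2 (0.686) or with quantile normalization. Proline and raffinose metabolism was lower (−0.32, 3 and 3 adjusted over the list alone), not so called without DIG1 replicate 2, DIG2 replicate 1 or DIG2 replicate 2 (up to 0.108). Flavonoid synthesis was higher (0.51, 0 and 3 adjusted over the list alone), not so called without DIG1 replicate 2 or DIG2 replicate 1 (up to 0.245). For these lists the camera adjusted p = 0.585 with an estimated correlation, and 0.643 for cell wall loosening. Fry, the limma test of movement one way on balance, called 0 of the 23 lists, where camera called 8 with the preset correlation and 0 with an estimated one, the latter with 2 lists at an unadjusted p under 0.05.

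Between the lines, 108 genes were higher and 302 lower in DIG1, of which 14 and 57 differed at least 2-fold. The counts were 20 and 106 without DIG1 replicate 1, 35 and 88 without DIG1 replicate 2, 42 and 144 without DIG2 replicate 1, and 163 lower without DIG2 replicate 2; they were 38 and 111 without the variance trend, and 65 were higher when only the 2 groups were fitted.

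Set side by side, the effects of DIG1 and DIG2 at 4 h overlapped. Leaving out the transgenes, 356 genes were higher in both lines and 583 lower in both, PORA, PORB, BBX23, RD20, COR6.6 and ABF3 among the latter and RD29A, NAC032 and DIN2 among the former. Independent lists of these sizes share 38.4 and 72.0 genes. A further 9 genes changed in opposite directions, with UMAMIT25 and AT1G26761 higher in DIG1 and the other 7, including LOX1 and HB-2, lower in DIG1; AT1G26761, LOX1 and HB-2 were picked as examples after their values were seen. The DIG2 call of PORB was lost without DIG2 replicate 1, and that of NAC032 without GFP replicate 2 or DIG2 replicate 1. Across 17369 genes, which are not independent replicates, the log2 changes correlated at a Pearson r of 0.72 and a Spearman rho of 0.67. Both lines were compared with the same 2 GFP libraries. In 50 simulated pairs of unchanged lines sharing such controls the mean r was 0.50 and at most 1 gene was lower in both. These pairs held no changed gene and so gave almost no calls. Their counts are thus no measure of the overlap between lines that each have changes of their own. The simulated noise was drawn for each gene on its own, so deviations shared by many genes were not simulated. The covariance of the log2 changes was 0.0939 against a simulated 0.0124, a difference of 0.0815. The GFP libraries are too few to split, so part of the excess in overlap may come from the shared controls. The overlaps were 164 higher and 288 lower without GFP replicate 1, 95 and 195 without GFP replicate 2, 172 and 365 without DIG1 replicate 1, 153 and 312 without DIG1 replicate 2, and 206 and 366 without DIG2 replicate 1; without the variance trend 206 were higher in both.

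**Figure D2:**
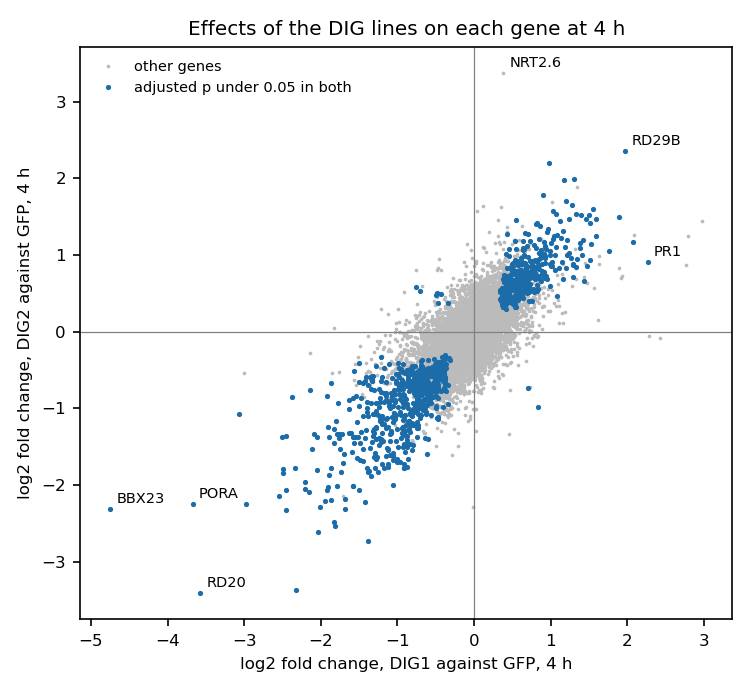
Log2 fold change against GFP at 4 h of each gene in DIG1 (x axis) and DIG2 (y axis), without the transgenes; blue points are genes with a limma adjusted p under 0.05 in both lines. Of the blue points 356 lie in the upper right and 583 in the lower left, and NRT2.6 stands out as high in DIG2.

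After 10 d in the light on dexamethasone, DIG1 seedlings differed from GFP seedlings in most genes measured. ICL, the isocitrate lyase of the glyoxylate cycle, rose from 13.9 ± 13.5 to 1316 ± 20 RPKM (log2 change 6.93 ± 0.72, limma adjusted p = 0.00114). DIN2 rose from 1.59 ± 0.761 to 125 ± 3.77 RPKM and DIN6, an asparagine synthetase gene of carbon starvation, from 2.32 ± 0.182 to 76.5 ± 6.99. VSP2, a jasmonate-induced storage protein gene, fell from 49.6 ± 9.11 to 0.0813 ± 0.0105 RPKM (−6.42 ± 0.17, limma adjusted p = 0.000155), the dehydrin gene ERD10 from 85.9 ± 0.999 to 0.962 ± 0.688, and the vacuolar aquaporin gene TIP2;2 from 240.1 ± 41.2 to 2.95 ± 0.498.

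The other largest rises were in GSTF3, BCAT-2, MPL1, TPX2 and CYP81D11, with log2 changes from 4.70 to 5.80. The other largest falls were in MLP328, SAG29, DR4, FUM2 and CDEF1, with log2 changes from −7.61 to −6.16. FUM2, the cytosolic fumarase gene, fell from 62.0 ± 3.94 to 0.324 ± 0.0421 RPKM. By the rule for naming genes, both DIG1 libraries lay beyond both GFP libraries in each of these 16 genes.

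**Figure D3:**
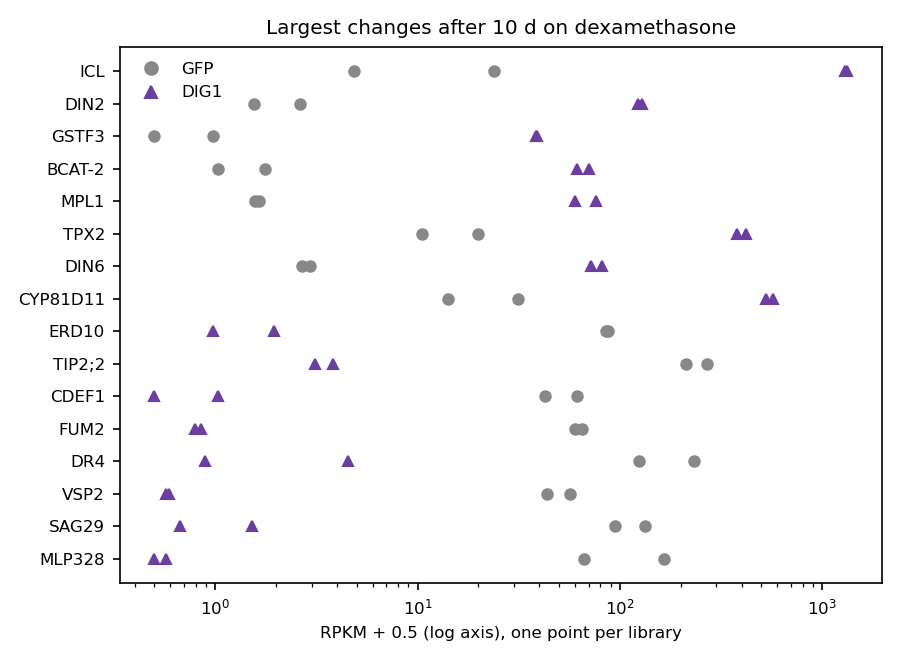
RPKM + 0.5 (log axis) after 10 d of the 8 genes with the largest rise and the 8 with the largest fall in DIG1; grey circles are the 2 GFP libraries and purple triangles the 2 DIG1 libraries. In every gene drawn the DIG1 libraries lie on one side of the GFP libraries, as the rule for naming genes requires.

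Photosynthesis genes were far lower at 10 d, with 19 of 20 falling over all genes tested and 20 adjusted over the list alone (mean −2.22, camera adjusted p = 6.37e-07; camera adjusted p = 0.586 with an estimated correlation). LHCB2.1 fell from 3234 ± 121 to 464 ± 3.61 RPKM and LHCB5 from 3728 ± 368 to 493 ± 53.4. Of the 20 most abundant genes in GFP, which include RBCS1A, CAB1 and RCA of photosynthesis, 19 fell and 0 rose. RBCS1A did not pass (limma adjusted p = 0.0697). These genes were chosen by their level in GFP, which favours falls. The 20 most abundant genes of each library, taken library by library and so not the same set, held 16.0% and 14.8% of all RPKM in the GFP libraries and 7.9% and 8.3% in DIG1. Aquaporin genes fell as a group (mean −2.07, 13 of 14 lower over all genes and 14 adjusted over the list alone, camera adjusted p = 5.87e-06; camera adjusted p = 0.586 with an estimated correlation). TIP1;1 fell from 827 ± 19.2 to 60.3 ± 11 RPKM. All 11 measured cell division genes fell, also adjusted over the list alone, CYCB1;2 from 12.9 ± 1.76 to 1.25 ± 0.263 RPKM and KNOLLE from 27.2 ± 7.42 to 3.14 ± 0.0643 (mean −2.15, camera adjusted p = 0.000111; camera adjusted p = 0.586 with an estimated correlation).

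Other lists that fell at 10 d had counts that were the same over all genes and adjusted over the list alone. They were flavonoid and anthocyanin synthesis (12 of 13 genes lower, mean −2.82, camera adjusted p = 1.75e-05), jasmonate synthesis and response (10 of 13 lower and 1 higher, mean −2.40, camera adjusted p = 0.00455), cell wall loosening (9 of 13 lower, mean −2.12, camera adjusted p = 0.0191) and cytokinin response (5 of 6 lower, mean −1.25, camera adjusted p = 0.0216). With an estimated correlation each of these had a camera adjusted p = 0.586. DFR, of anthocyanin synthesis, fell from 63.1 ± 22.1 to 1.51 ± 0.576 RPKM, the lipoxygenase gene LOX2 from 86.9 ± 16.7 to 2.19 ± 1.65, and the cytokinin-response gene ARR6 from 10.8 ± 0.764 to 2.35 ± 0.568. Root markers moved with these groups. Of their 9 measured genes 7 fell (7 adjusted over the list alone), with a mean log2 change of −3.11 (camera adjusted p = 0.00482; camera adjusted p = 0.586 with an estimated correlation). The phosphate transporter gene PHT1;1 fell from 38.9 ± 4.47 to 0.666 ± 0.279 RPKM and CASP1, of the root endodermis, from 17.7 ± 5.78 to 1.64 ± 0.665. Of 5 guard cell markers 1 rose and 3 fell (1 and 4 adjusted over the list alone), which did not pass camera (mean −1.54, adjusted p = 0.199).

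ABA- and drought-induced genes fell at 10 d, 11 of 17 over all genes and adjusted over the list alone and none rising (mean −3.04, camera adjusted p = 0.000525; camera adjusted p = 0.594 with an estimated correlation; fry adjusted p = 0.0566). COR47 fell from 164 ± 31.4 to 7.31 ± 1.16 RPKM and KIN1 from 39.2 ± 7.91 to 0.366 ± 0.517. The signalling genes upstream moved both ways, as did all genes tested, of which 5560 of 17433 rose and 5439 fell. Of 9 measured ABA receptors 4 rose and 4 fell, with a mean of 0.30 and a median of −0.04, with the same counts adjusted over the list alone and camera pointing down (adjusted p = 0.876), PYL4 rising from 57.4 ± 22.9 to 183 ± 31.1 RPKM and PYL9 falling from 7.38 ± 0.171 to 3.70 ± 0.262. Of 7 clade A phosphatases, which restrain ABA signalling, 1 rose (HAB1) and 3 fell (HAI1, AHG3 and HAI2), also adjusted over the list alone (camera adjusted p = 0.199). SNRK2.2 and SNRK2.3 were among 4 of 9 SnRK2 kinases that rose, and 3 fell, also adjusted over the list alone (mean −0.08, median 0.11, camera adjusted p = 0.586). Of 22 ABA transcription factors 10 rose and 7 fell (11 and 7 adjusted over the list alone; mean −0.27, median 0.22, camera pointing up with adjusted p = 0.876), ABF3 falling from 61.7 ± 6.61 to 3.52 ± 0.393 RPKM. In ABA synthesis and turnover 6 of 10 genes fell, NCED3 and ABA2 among them, and none rose, also adjusted over the list alone (mean −1.09, camera adjusted p = 0.0722). The seed maturation list had 1 measured gene, the oleosin gene OLEO4, which fell from 6.01 ± 0.731 to 0.115 ± 0.162 RPKM (limma adjusted p = 0.000499).

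Lists with more rises than falls at 10 d did not pass camera, and their counts were the same adjusted over the list alone unless given. In senescence and sugar starvation 8 of 11 genes rose and 3 fell (mean 1.19, adjusted p = 0.0798), and in the circadian clock 8 of 12 rose and 3 fell (mean 0.69, adjusted p = 0.118), with ELF3 rising from 6.13 ± 0.378 to 37.3 ± 2.44 RPKM and LHY falling from 70.8 ± 10.6 to 17.0 ± 0.253. In cold and touch response 3 of 4 rose and 1 fell (camera adjusted p = 0.199), TCH3 from 6.76 ± 4.54 to 77.1 ± 20.8 RPKM and ZAT10 from 3.15 ± 1.26 to 33.1 ± 0.749. In heat shock proteins 4 of 8 rose and 1 fell (camera adjusted p = 0.199), with HSP23.6 rising from 0.170 ± 0.108 to 16.0 ± 2.25 RPKM. In salicylic acid and defence 4 of 8 rose, WRKY33 and NPR1 among them, and 2 fell, EDS1 included (5 and 2 adjusted over the list alone, camera adjusted p = 0.295). In proline and raffinose metabolism 5 of 8 rose and 3 fell (mean 0.01, median 1.34, camera adjusted p = 0.295), with P5CS2 rising and RS5 falling. Of 8 auxin response genes 1 rose and 4 fell (camera adjusted p = 0.107), and of 6 light response genes 3 rose and 2 fell, with a mean of −0.54 and a median of −0.10 while camera pointed up (adjusted p = 0.868). Fry, which asks whether a list's genes move one way on balance, called some lists that camera did not. Those it called up were senescence and the clock (fry adjusted p = 0.0193 for both), proline and raffinose metabolism (0.0289) and light response (0.0379, against the sign of its mean and median). Those it called down were guard cell markers (fry adjusted p = 0.0193), ABA synthesis and turnover (0.0289) and auxin response (0.0326). Heat shock proteins, cold and touch response and salicylic acid and defence did not pass fry either (adjusted p = 0.0635, 0.0725 and 0.190).

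At 10 d 5560 of 17433 genes rose and 5439 fell in DIG1, of which 1757 and 3315 changed at least 2-fold. All 9 called lists kept their call without each of the 4 libraries in turn.

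**Figure D4:**
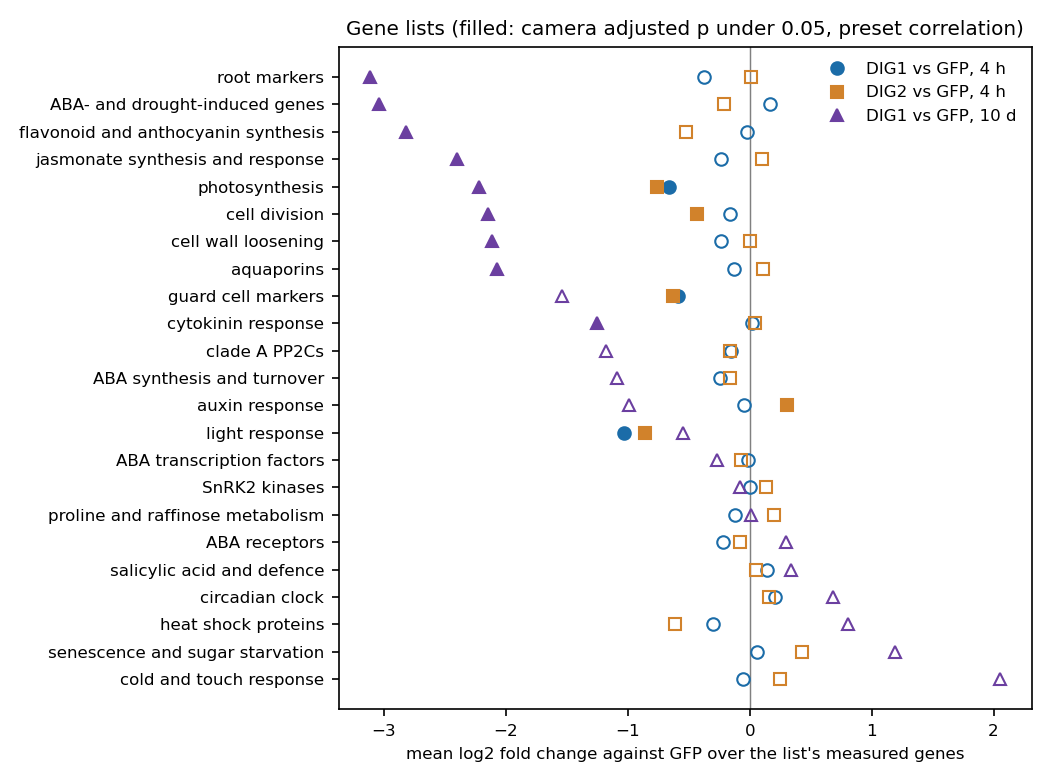
Mean log2 fold change against GFP of the measured genes of each list for DIG1 at 4 h (circles), DIG2 at 4 h (squares) and DIG1 at 10 d (triangles); filled symbols have a camera adjusted p under 0.05 with the preset correlation. Photosynthesis genes lie at −0.66, −0.76 and −2.22, left of 0 in all 3 comparisons.

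Set against each other, the DIG1 effects at 4 h and 10 d shared part of their genes, over 16392 genes listed in both tables and with the transgene left out. Of the genes called at both, 655 were lower at both, ABF3, LHCB2.1, PORB and JAZ1 among them, against 247.6 for independent lists (one-sided Fisher's exact test, p = 4.02e-197). Higher at both were 268 genes, DIN2 among them, against 158.3 (p = 2.31e-25 in the same exact test). The exact test takes genes as independent, which they are not. Another 87 rose at 4 h and fell at 10 d, such as NRT2.1, whose call at 4 h was lost without any of the 4 libraries (limma adjusted p up to 0.178), and 51 fell at 4 h and rose at 10 d, such as PHYA. Across genes, which are not independent replicates, the log2 changes correlated at a Pearson r of 0.46 and a Spearman rho of 0.42. The 2 experiments differ in age, light, dose and duration together, and beyond these overlaps of calls the size of the effects was not tested between the tables. The overlaps were 137 higher and 337 lower without GFP replicate 1 at 4 h, 76 and 225 without GFP replicate 2, 119 and 397 without DIG1 replicate 1, and 119 and 302 without DIG1 replicate 2; without the variance trend 158 were higher.

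In the authors' deposited table for 4 h, 719 genes were higher and 1229 lower in DIG1 and 1629 and 1634 in DIG2 at an FDR under 0.05, and in the authors' deposited table for 10 d 5500 were higher and 5418 lower. Of the calls made here, 97.4%, 97.7% and 95.4% were also called in the authors' deposited table with the same sign, and 0 with the opposite sign.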

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

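As tests of explanations, those of light-lowered genes, of simulated unchanged lines, of the photosynthesis list and of quantile normalization were chosen only after the result was seen, while the contrast of the lines, its list tests, the fits with a library left out and quantile normalization as a setting were planned.

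In 12 named genes both DIG1 libraries lay beyond both GFP libraries at 4 h and at 10 d, in opposite directions. The difference itself was not tested. With 2 libraries per group, unchanged genes are often separated in this way by chance, and the number expected was not worked out. Of the 12 genes, only NRT2.1, RVE8 and PHYA passed limma at both times. The DIG1 libraries lay above those of GFP at 4 h and below them at 10 d for NRT2.1 (log2 change at 10 d −2.07), RVE8 (−0.60), EXPA5 (−4.12), SAUR20 (−2.38), NF-YB2 (−3.17), CYP707A3 (−1.24), PER4 (−0.78) and FBH3 (−0.49). They lay below at 4 h and above at 10 d for PHYA (1.25), P5CS2 (1.72), WRKY33 (1.87) and FAMA (0.33). At 4 h EXPA5, SAUR20, NF-YB2, CYP707A3, P5CS2, WRKY33 and FAMA did not pass (limma adjusted p from 0.0603 for P5CS2 to 0.726 for CYP707A3), and at 10 d PER4 and FBH3 did not (limma adjusted p = 0.0787 and 0.136). The limma call at 4 h was lost without any of the 4 libraries for NRT2.1 (adjusted p up to 0.178) and FBH3 (up to 0.0898), and without GFP replicate 1, GFP replicate 2 or DIG1 replicate 2 for RVE8 (up to 0.0888). The limma call of FAMA at 10 d was lost without any of the 4 libraries (adjusted p up to 0.143).

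The DIG1 and DIG2 effects differed at 4 h by the direct contrast of the lines (limma). The log2 difference, DIG1 minus DIG2, was positive for UMAMIT25 (1.82), EXPA2 (1.47), PR1 (1.35), ELIP2 (1.35) and GSTF6 (1.28). It was negative for NRT2.6 (−3.00), BBX23 (−2.44), BBX17 (−2.0), PGAZAT (−1.53), GH3.1 (−1.52), PRODH2 (−1.56), PRODH1 (−0.59), P5CS2 (−0.53), PIL1 (−1.02), PORA (−1.42), PHYA (−0.67), XTH19 (−1.08), SAUR22 (−0.64), IAA5 (−0.80), AOC1 (−0.88) and DIN2 (−0.80). Some of these limma calls were lost with 1 library left out. Leaving out any of the 4 ended the calls of EXPA2 (adjusted p up to 0.192), PRODH1 (0.0862), P5CS2 (0.112), PHYA (0.106), IAA5 (0.193) and AOC1 (0.111). Leaving out DIG1 replicate 1, DIG1 replicate 2 or DIG2 replicate 1 ended those of PR1 (0.141), GSTF6 (0.0791) and DIN2 (0.121), and either DIG1 library or DIG2 replicate 2 that of SAUR22 (0.0865). The call of PGAZAT was lost without either DIG1 library, and those of GH3.1 and PRODH2 without DIG1 replicate 1. Such fits have fewer samples, so a lost call does not single out the library left out.

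By camera with the preset correlation, mean differences over lists, DIG1 minus DIG2, were −0.35 for auxin response and 0.27 for cell division. The other list differences were called in the full fit and lost without some library. They were −0.32 for proline and raffinose metabolism (camera adjusted p up to 0.108 without DIG1 replicate 2, DIG2 replicate 1 or DIG2 replicate 2), −0.24 for cell wall loosening (0.686 without DIG2 replicate 2), −0.34 for jasmonate (0.0624 without DIG1 replicate 1), −0.36 for senescence and sugar starvation (0.113 without DIG2 replicate 1), −0.39 for root markers (up to 0.576 without DIG1 replicate 1 or DIG2 replicate 2) and 0.51 for flavonoid synthesis (up to 0.245 without DIG1 replicate 2 or DIG2 replicate 1). No list kept its call with an estimated correlation.

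At 4 h in the dark, 5 (DIG1) and 8 (DIG2) of 20 photosynthesis genes and 6 and 5 of 8 light response genes fell. HY5 rose in both lines, though in DIG1 its call was lost without GFP replicate 1 or either DIG1 library. The camera calls of both lists were lost with an estimated correlation (adjusted p = 0.9398 and 0.744 for photosynthesis, 0.362 and 0.414 for light response). By fry the light response list passed in both lines (adjusted p = 0.00204 and 0.0033) and the photosynthesis list in neither (0.140 and 0.0667). Exposure of the GFP seedlings to light stays open: PORA, PHYA and PIL1, which light lowers and which would then be higher in the DIG lines, had a mean log2 difference of −1.23 (standard error over the genes 0.869), but they belong to the list in question, and DIN2, which darkness induces, rose in both lines. Chance spread of the shared GFP libraries stays open. Simulated unchanged lines gave at most 1 gene lower in both, against 583. Lines without any changed gene give almost no calls, so this count cannot decide. The covariance of the log2 changes over all genes was 0.0939, against a simulated highest of 0.0136. That argues against spread independent between genes as the whole cause of the likeness over all genes. Deviations of the GFP libraries shared by many genes were not simulated. A difference of the GFP line or its growth that has nothing to do with the DIG proteins cannot be told apart from a shared DIG effect, because every comparison with GFP rests on the same 2 libraries, and the mean difference of the photosynthesis list between the lines, 0.0955, is what either would give. Repression of light-regulated genes by both DIG proteins thus stays a hypothesis.

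More than 10000 genes differed in DIG1 at 10 d. Scaling is argued against as the cause, since quantile normalization, which gives every library the same distribution, called 11208 genes. A smaller share of root as the whole cause is argued against by the photosynthesis list, which would rise with it and had a mean log2 change of −2.22 (standard error 0.23). A candidate explanation is that DIG1 seedlings were still using seed lipid, as in an early or arrested stage: a list written after ICL was seen, but before its members were looked at, had a mean log2 change of 0.80 (standard error 0.24), with 10 of 12 genes higher, MLS from 3.08 ± 0.469 to 14.7 ± 2.74 RPKM and PCK1 from 71.6 ± 3.82 to 287 ± 16.9, and 1, PMDH2, lower. Against an earlier stage stands the oleosin gene OLEO4, which fell by 3.43 on the log2 scale, and carbon starvation, in which such genes may also rise, was not separated from it.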

How the results depend on the processing

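The fit with voom weights was chosen only after the result was seen; it and the settings not named here kept each count of genes within 1.5 times. SLAC1 at 10 d changed sign with quantile normalization (0.0538, where the median of all genes was 0.132), and no other named gene or list that passed its test did so in the settings run; the cause was not tested. Means of lists without a call changed sign under some settings. The cause was not tested for the variance trend either. Without it, 329 genes rose in DIG1 and 762 in DIG2 at 4 h, 38 were higher and 111 lower between the lines, 206 were higher in both lines and 158 higher in DIG1 at both times. Fitted alone, DIG1 was higher than DIG2 in 65 genes, with fewer samples to estimate the spread. A 2-fold minimum, which only removes calls, left 75 and 263 genes in DIG1, 107 and 273 in DIG2, 14 and 57 between the lines and 1757 and 3315 at 10 d. With an estimated correlation camera called 0 lists in each comparison, with 1, 2, 2 and 1 lists at an unadjusted p under 0.05; fry called 4, 4, 0 and 15 (DIG1, DIG2, between the lines, 10 d), which include 2 of the 3, 3 of the 5, 0 of the 8 and 8 of the 9 lists that camera called with the preset correlation.

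With 1 library left out, which leaves fewer samples, the number of genes higher and lower ranged from 141 to 254 and 335 to 587 in DIG1 at 4 h, 406 to 926 and 509 to 1086 in DIG2, 20 to 87 and 88 to 163 between the lines, and 3862 to 4592 and 4227 to 4917 at 10 d. Camera called 2 to 3, 4 to 6, 6 to 10 and 9 to 12 lists in the same order. The lines shared 95 to 295 higher and 195 to 531 lower genes (r from 0.645 to 0.763), and DIG1 at both times 76 to 255 and 225 to 647 (r from 0.420 to 0.460). Of the fits of named genes with 1 library left out, 834 kept their side of the threshold, 173 lost the call and 1 gained it.

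Whether the replicate numbers pair the samples is not settled. At 4 h, deviations of same-numbered libraries correlated at 0.0166 (GFP and DIG1), 0.163 (GFP and DIG2) and −0.00882 (DIG1 and DIG2). At 10 d they correlated at 0.0412 (GFP and DIG1). With the replicate number as a block, 580 and 1050 genes were higher and lower in DIG1, 1384 and 1399 in DIG2, 139 and 339 between the lines and 5231 and 5297 at 10 d, with 3, 7, 7 and 9 lists. Depth was not varied; the tables hold few genes under 2 CPM, so nothing is shown of genes below that level, and the 2 libraries of DIG1 at 4 h had the fewest recovered reads (9481472 and 9841051).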

Other observations

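The tests of gene families and of neighbouring genes below were chosen only after the result was seen, except that on tandem copies by annotated product.

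Families of at least 10 genes, formed from the annotation's symbols and product names, were tested with camera, 266 of them at 10 d and 258 in each line at 4 h. After 10 d DIG1 seedlings had lower transcripts in several families. Of 44 lipid-transfer protein genes 40 fell (mean log2 change −3.47, camera adjusted p = 2.15e-11), of 42 peroxidase genes 36 fell (mean −2.44, camera adjusted p = 3.86e-08), and of 26 histone genes 22 fell and 1 rose (mean −1.25). Fasciclin-like FLA genes (12 of 13 lower, mean −2.45) and laccase LAC genes (10 of 11 lower, mean −2.51) fell as well. Pentatricopeptide repeat genes, most of which act on RNA in plastids and mitochondria, went the other way, with 91 of 156 higher and 2 lower (mean 0.60, camera adjusted p = 1.64e-07). All these directions were the same with quantile normalization and with a median shift. None of the 266 families kept a call with an estimated correlation (smallest camera adjusted p = 0.7125), where camera called 56 with the preset one, and families were not rerun with libraries left out.

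At 4 h, in DIG1, 9 of 20 XTH genes of cell wall remodelling fell and 1 rose (mean −0.55, camera adjusted p = 0.000159), and 5 of 11 BBX genes of light signalling fell (mean −0.77, camera adjusted p = 0.00219). In DIG2, 13 of 42 SAUR-like genes of auxin response rose and 3 fell (mean 0.30, camera adjusted p = 0.00015), and 7 of 40 WRKY genes, many of them active in defence, rose and 2 fell (mean 0.23, camera adjusted p = 0.00322). The directions were the same with both other scalings. With an estimated correlation camera called 0 families in either line (smallest adjusted p = 0.98515 in DIG1 and 0.83735 in DIG2), against 12 and 13 with the preset correlation.

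Genes called lower in DIG1 at 4 h lay next to each other more often than random placement gives: among 17295 placed genes, 89 pairs of adjacent listed genes were both called lower, against a mean of 53.3 and a highest of 84 in 10000 permutations of the calls (one-sided permutation p = 0.0001, the smallest they can give). Tandem copies of a family are argued against as the whole cause, since 81 pairs were left without pairs of the same annotated product (permuted mean 51.8, highest 80, permutation p = 0.0001). With pairs that share a symbol stem or at least 3 peptide words of 5 residues left out as well, 73 remained (permuted mean 50.1, highest 79, permutation p = 0.001), above the permuted mean but not above the highest of the permutations, so copies may make up part of the excess. A change shared by neighbouring genes stays a hypothesis, and genes that overlap, 8 of the pairs, may share reads. Without pairs of the same product there were 28 pairs higher in DIG1 (permuted mean 15.3, highest 30, permutation p = 0.001), and 138 lower (permuted mean 93.6, highest 128) and 131 higher (permuted mean 92.1, highest 126) in DIG2, and with the wider rule on families 22 (permuted mean 14.8, highest 31, permutation p = 0.0456), 132 (permuted mean 90.5, highest 128) and 113 (permuted mean 89.1, highest 123).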
